A study of Mus musculus with 6 samples.

How the data were processed

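RNA-seq was carried out on 6 libraries of cultured CAFs, 3 labelled WT and 3 labelled Thbs2KO. Per the labels' protocols, cells were grown on fibronectin-coated plates in serum-containing medium, RNA was column-purified with DNase treatment, and libraries were made with a TruSeq RNA v2 kit, which does not mark strand. Without strand, reads where a gene and an antisense gene overlap cannot be assigned to either. The authors deposited expected counts, the reads per gene as estimated by RSEM, not scaled between samples. Per the submitters' processing notes, Trimmomatic 0.39, STAR 2.7.3a and RSEM were used with mm10; the RSEM version and the annotation release are not given in the sources used here. RSEM divides a read that matches several genes among them by an estimate, so a gene and its near-identical copies share uncertainty. From 3.80% to 3.88% of the values per library were not whole, and values were rounded to whole numbers before testing.

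The table holds 55401 genes in 6 columns, each named for its sample in the labels. Genes passing filterByExpr (13590) were kept, and the libraries' totals were scaled with TMM. The comparison of Thbs2KO with WT used the quasi-likelihood test of edgeR 4.0.16 (robust, genotype as the only term) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05; every adjusted p of a gene comes from that fit. CPM values use TMM factors, and errors are SD over 3 libraries. Standard errors of log2 fold changes were derived from the fit's F statistic. The exact permutation test of Thbs2 was two-sided. Gene positions and types come from GENCODE M21 (GRCm38, the same build as mm10), joined by Ensembl identifier without version, which placed 99.96% of tested genes.

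Before the data were examined, 20 process lists, 9 cell type lists, quality lists, the tests, the alternatives and a rule for named genes were fixed. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a correlation of 0.01 between genes, adjusted over the lists of a kind, and again with the correlation estimated. The limma test fry, also fixed beforehand, asks whether a list moves without comparing it with other genes. Its p is given unadjusted. The naming rule took Thbs2, then the 12 largest increases and 12 largest decreases among changed genes with a mean of at least 5 CPM, groups that do not overlap and a symbol that is not a predicted name; 48 increases and 62 decreases qualified. It then took up to 3 changed members of each process list or, where none changed, the 2 with the smallest p, given as values. Protein-coding matches of pseudogene transcripts were sought with BLAST+ 2.17.0 (same strand, E-value up to 1e-20, at least 90% identity over at least 50% of the copy).

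Thbs2KO replicates 1 and 2 were the most alike pair of libraries, with a chi-square per degree of freedom of 3.88 over genes, against 15.6 to 121.7 for the other pairs. This does not show whether they are separate samples or 2 preparations of 1 sample; they were kept as 2, as the labels list them, and summed in an alternative. The first principal component held 46.0% of the variance and separated the genotypes; the second (27.9%) set WT replicate 1 and Thbs2KO replicate 3 apart from the others. The steps were tested on simulated counts with the real means, library sizes and dispersions: for the comparison of Thbs2KO with WT over 13590 genes with 200 changed, the edgeR step called 13 of 50 genes changed 1.5-fold, 44 of 50 changed 2-fold, 49 of 50 changed 4-fold and 47 of 50 changed 8-fold, with 7 unchanged genes called and 0 called when no gene was changed. The simulation drew each gene independently, made no pair of libraries within a group more alike than another, and changed only genes of at least 5 CPM. Alternatives tried were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter, a stricter filter, no robust estimation, a replicate block, a tested minimum of 1.5-fold, and each library left out. Other alternatives were added after the data were examined: both WT replicate 1 and Thbs2KO replicate 3 left out, Thbs2KO replicates 1 and 2 summed, protein-coding genes only, and no genes of chromosome 17. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.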

Results

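RNA-seq was carried out on cancer-associated fibroblasts (CAFs), the activated fibroblasts of a tumour, cultured after isolation from tumours that had grown from mouse tumour organoids placed orthotopically in the rectum. The host mice were wild type (WT) or lacked a functional Thbs2 gene (Thbs2KO), which encodes the secreted matricellular glycoprotein thrombospondin-2. There were 6 libraries in 2 groups, 3 WT and 3 Thbs2KO. Total expected counts were 23986332, 23061568 and 24417464 in WT replicates 1, 2 and 3, and 20289615, 19649066 and 20860335 in Thbs2KO replicates 1, 2 and 3. The labels do not say whether the replicates are separate mice or separate cultures, so p-values measure only the spread between these libraries, which may be technical. The comparison asks which transcripts differ between CAFs isolated from Thbs2KO hosts and CAFs isolated from WT hosts.

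Thbs2 (ENSMUSG00000023885.9, chromosome 17, 14665500 to 14694235, minus strand, mm10) was measured first, as a check of the labels. Its normalised read count, scaled to library size (CPM), was 2327, 4166 and 3705 in the WT libraries and 538.2, 424.7 and 412 CPM in the Thbs2KO libraries. The mean fell from 3399 ± 957 CPM in WT to 458.3 ± 69.5 CPM in Thbs2KO (SD, n = 3 each), a log2 fold change of -2.89 with a standard error of 0.246 (edgeR, Benjamini-Hochberg adjusted p = 0.00521). Every Thbs2KO library lay below every WT library, and the two-sided exact permutation p was 0.1, the smallest that 3 against 3 allows. The Thbs2KO libraries kept 15.8%, 12.5% and 12.1% of the WT mean.

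Genes that fell included Ccn2, Fgf2, Ntn4 and Gjb2. Ccn2, a matricellular protein induced by TGF-beta and by mechanical tension, fell from 1704 ± 458 to 586.5 ± 57.9 CPM (log2 fold change -1.54, SE 0.209, edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.0299). Its relative Ccn5 fell from 53.2 ± 13.8 to 15.96 ± 0.107 CPM, and Ltbp2, a latent TGF-beta binding protein family member of elastic microfibrils, from 1040 ± 254 to 384.9 ± 54.3 CPM. Fgf2, a fibroblast growth factor that promotes angiogenesis, fell from 179.2 ± 25.01 to 56.9 ± 3.33 CPM (log2 fold change -1.66, SE 0.115, edgeR, Benjamini-Hochberg adjusted p = 0.00201). Fgf2os, an antisense transcript that overlaps Fgf2, also fell, and reads of the shared part cannot be assigned to a strand. Ntn4, a laminin-related netrin of basement membranes, fell by 4.26 on the log2 scale, from 91.2 ± 37.9 to 4.76 ± 0.299 CPM. Gjb2, the gap junction protein connexin 26, fell from 27.6 ± 5.02 to 6.72 ± 0.786 CPM, and Sik1, Fhdc1, Tbc1d2, Cmah and Rnaset2b had log2 fold changes of -1.99, -2.61, -1.99, -1.60 and -1.66. The largest decrease under the naming rule was that of AI506816, a noncoding transcript on chromosome 5, from 393.7 ± 55.0 to 4.68 ± 1.58 CPM (log2 fold change -6.39, SE 0.284, edgeR, Benjamini-Hochberg adjusted p = 0.000261; all n = 3 per group, SD).

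Genes that rose included Apoe, the lipid carrier apolipoprotein E, from 3.53 ± 0.451 CPM in WT to 198.3 ± 127.6 CPM in Thbs2KO (log2 fold change 5.81, SE 0.522, edgeR, Benjamini-Hochberg adjusted p = 0.00579). Apoe measured 115.9, 133.6 and 345.3 CPM in Thbs2KO replicates 1, 2 and 3. With 1 library left out its log2 fold change ran from 5.14 to 6.08. Cd200, a surface glycoprotein whose receptor restrains myeloid cells, rose from 0.751 ± 0.685 to 24.2 ± 2.02 CPM. Thsd4, a thrombospondin type 1 repeat protein of microfibrils, rose from 7.42 ± 0.876 to 80.0 ± 20.4 CPM, and the netrin receptor gene Unc5c from 2.85 ± 1.99 to 35.2 ± 7.15 CPM. The secreted semaphorin Sema3c rose from 28.0 ± 7.71 to 186.7 ± 51.6 CPM (log2 fold change 2.74, SE 0.276, edgeR, Benjamini-Hochberg adjusted p = 0.00967). A set of 12 further rising protein-coding genes was chosen after their values were seen, because copies of other genes fill most of the places that the naming rule gave to increases. That set holds Sema3c and Ltbp1, which the rule names through their lists, and Pgm5, Slc14a1, Srp54b, Glp1r, Uggt2, Prex2, Rtl3, Coro2b, Dixdc1 and Shox2, with log2 fold changes from 1.49 for Shox2 to 3.23 for Pgm5. Srp54b and Rnaset2b have close relatives in the genome, so their counts depend on how shared reads were divided.

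**Figure D1:**
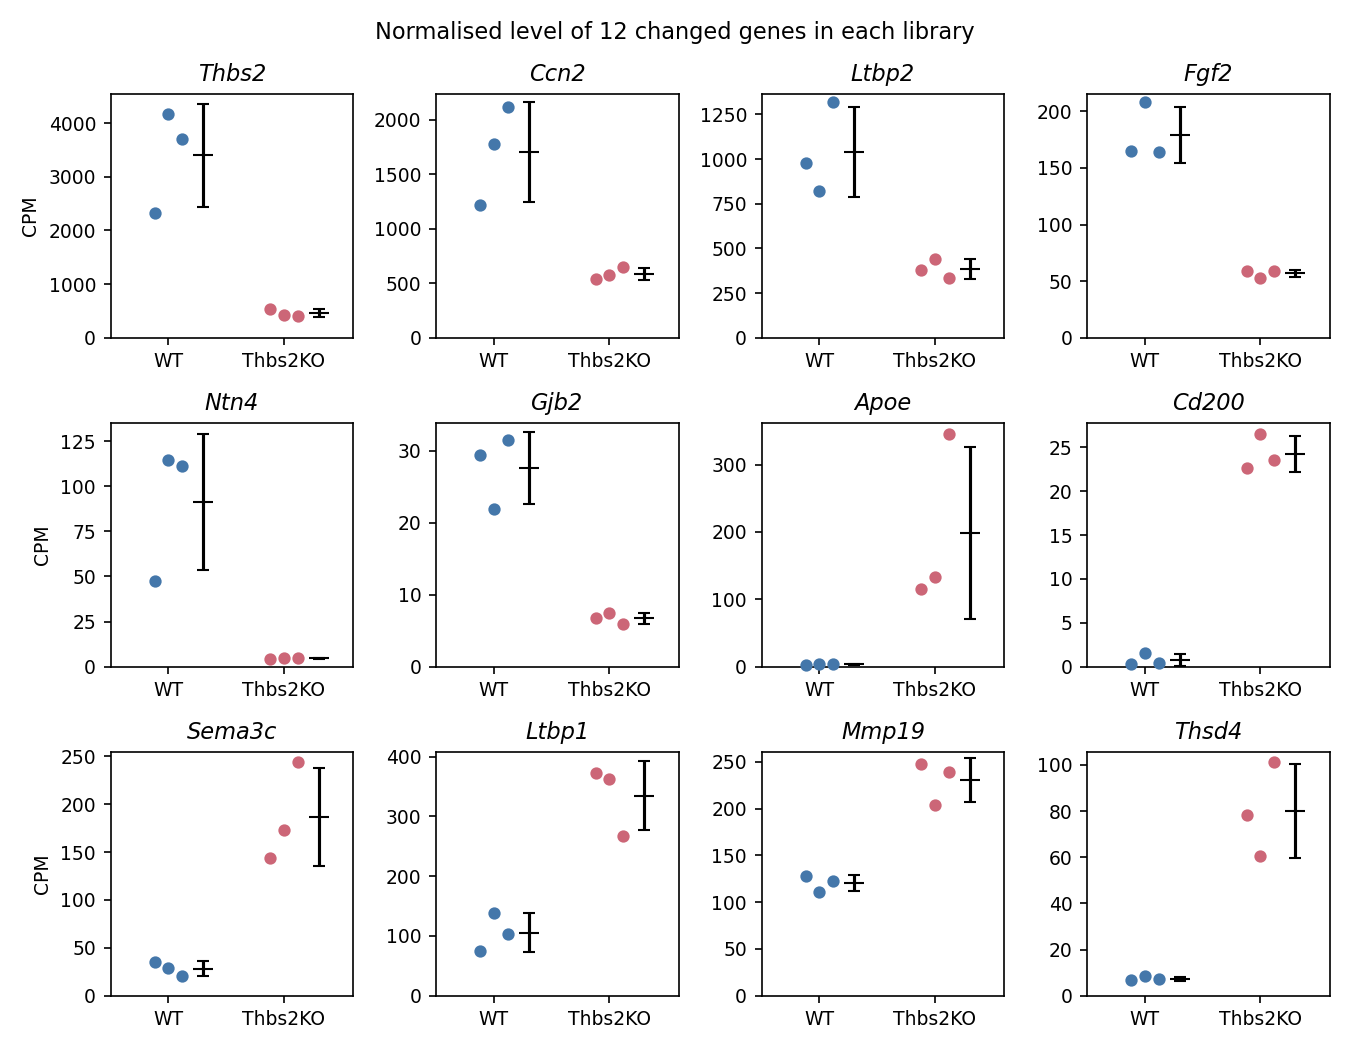
Normalised level in CPM (vertical axes, linear, starting at 0) of 12 changed genes in the 3 WT libraries (blue) and the 3 Thbs2KO libraries (red), with the group mean and SD (n = 3) as black bars. For each gene the groups do not overlap; Apoe stands at 198.3 ± 127.6 CPM in Thbs2KO.

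In total, 148 of 13590 tested genes changed, 75 higher and 73 lower in Thbs2KO (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), of which 58 rose and 38 fell by more than 2-fold. Protein-coding genes made up 114 of them, 50 higher and 64 lower. The 6 lincRNAs were all lower. The groups did not overlap for any of the 148 genes. Over all tested genes this held for 2671, or 19.7%, against the 10% that chance gives with 3 against 3 independent libraries. If Thbs2KO replicates 1 and 2 are 2 preparations of 1 sample, chance gives a higher share, so an excess is not shown. Libraries decided the count: leaving out WT replicate 1 gave 397 genes, and leaving out WT replicate 2, WT replicate 3, Thbs2KO replicate 1 or Thbs2KO replicate 2 gave 79, 49, 38 or 45. DESeq2 gave 699, and leaving out both WT replicate 1 and Thbs2KO replicate 3, chosen after the data were examined, gave 1519. With Thbs2KO replicates 1 and 2 summed, the most alike pair of libraries and an alternative also chosen after the data were examined, 40 genes changed, and 23 of the named genes lost their call. Of the 45 changed genes that the text names, including those chosen after their values were seen, 19 passed the threshold with each library left out in turn. Cd200, Ntn4, Ccn2, Ccn5, Ltbp2, Ltbp1, Unc5c, Mmp19 and Cyp51 were among the 26 that did not, with highest edgeR Benjamini-Hochberg adjusted p of 0.0709, 0.0544, 0.164, 0.0859, 0.164, 0.174, 0.164, 0.0829 and 0.211. Pgm5 lost its call with each of the 6 libraries left out (edgeR Benjamini-Hochberg adjusted p from 0.0539 to 0.171). Slc14a1, Tbc1d2, Sik1 and Cmah lost theirs in 4, 4, 5 and 5 of these fits. Named genes lost 26 calls without Thbs2KO replicate 1, 22 without Thbs2KO replicate 2, 16 without Thbs2KO replicate 3, 18 without WT replicate 3, 11 without WT replicate 2 and 2 without WT replicate 1. Rps3a1, Atp6v0c, Rnps1, Fgf2os, Zdhhc14 and Rsph3a, all chosen after their values were seen, were among them, with highest edgeR Benjamini-Hochberg adjusted p of 0.081, 0.102, 0.154, 0.172, 0.119 and 0.0544.

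Many of the strongest increases were in pseudogenes, most of them processed, that is intronless copies of protein-coding genes: 21 of the 22 changed pseudogenes were higher in Thbs2KO. Rps3a3 (chromosome 13, 108670603 to 108671397) rose from 0.145 ± 0.154 to 164.8 ± 3.80 CPM and Rps3a2 (chromosome 14, 88123017 to 88123808) from 17.03 ± 0.814 to 321.8 ± 7.07 CPM. Both resemble Rps3a1, a ribosomal protein gene on chromosome 3, which fell from 838.5 to 467.6 CPM (edgeR, Benjamini-Hochberg adjusted p = 0.00702). Rpl34-ps1, Rps2-ps6, Atp6v0c-ps2, Tdg-ps2 and Rnps1-ps had log2 fold changes of 7.42, 6.10, 5.74, 4.25 and 4.15. Atp6v0c and Rnps1, the protein-coding genes that Atp6v0c-ps2 and Rnps1-ps resemble, fell from 281.1 to 172.4 CPM and from 102.4 to 60.4 CPM. These genes and Rps3a1 were chosen after their values were seen, as was Fgf2os. Hmga1b, annotated as protein-coding and a near copy of the chromatin protein gene Hmga1, rose with a log2 fold change of 4.16, so its level is uncertain in the same way. The best protein-coding match of each of the 21 rising pseudogenes was 96.4% to 100% identical, so the levels of the copies and of the genes they resemble are uncertain.

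**Figure D2:**
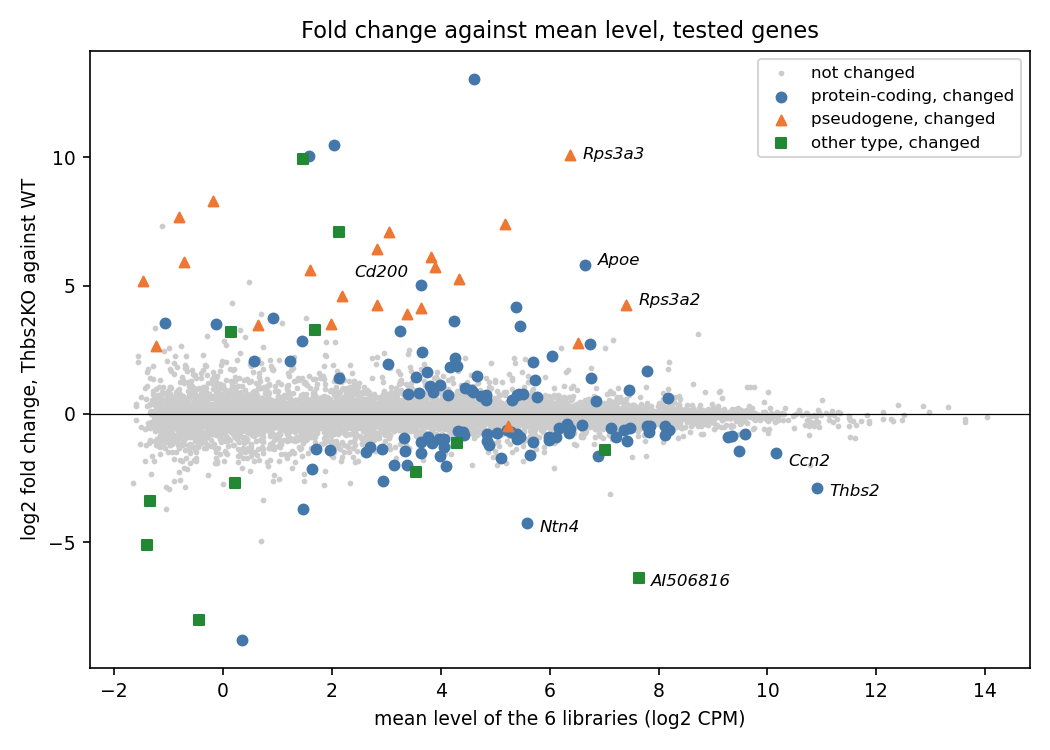
Log2 fold change of Thbs2KO against WT (vertical axis) against mean level of the 6 libraries in log2 CPM (horizontal axis) for 13590 tested genes. Changed genes are blue circles (protein-coding), orange triangles (pseudogenes) or green squares (other types); 21 of the 22 triangles lie above 0.

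Genes of the contractile and myofibroblast list, fixed before the data were examined, were lower in Thbs2KO as a group by camera with a preset correlation of 0.01 (Benjamini-Hochberg adjusted p = 2.31e-09). They did not pass with it estimated (adjusted p = 0.696 with an estimated correlation). Of 20 tested members 19 had negative log2 fold changes, with a median of -0.69. By edgeR 0 changed over all genes, 16 were lower at an unadjusted p under 0.05 and 16 when adjusted over the list alone. DESeq2 called 11 lower. Myh9, the heavy chain of nonmuscle myosin, measured 3360 ± 331 CPM in WT and 2438 ± 135 CPM in Thbs2KO, and the calponin Cnn2 620.6 ± 84.5 and 438.5 ± 24.2 CPM (SD, n = 3). Acta2, smooth muscle actin and chosen after its values were seen, measured 2289, 4345 and 4868 CPM in the WT libraries and 1832, 2028 and 2267 CPM in the Thbs2KO libraries. WT replicate 1 thus lay close to the Thbs2KO libraries: as mean log2 CPM relative to the 6 libraries, the list stood at -0.24, 0.72 and 0.58 in WT and -0.49, -0.35 and -0.23 in Thbs2KO. In the pericyte and smooth muscle marker list, 6 of 12 tested members were lower when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.0738). Of these 6, 4 are also members of the contractile list (Myh11, Actg2, Cnn1 and Lmod1), as is Des, so the lists are not independent. The marker list was lower by camera at the preset correlation without WT replicate 1 (adjusted p = 0.00271), whose level in it was -0.43. With all libraries it had an adjusted p = 0.841 with an estimated correlation.

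A further 3 of the 20 process lists were lower by camera. In the YAP and SRF target list, 15 of 17 tested members had negative log2 fold changes (median -0.26). Ccn2 fell, and 2 members were lower when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.000316; adjusted p = 0.27 with an estimated correlation). In cholesterol biosynthesis, 22 of 24 were negative (median -0.14), and Cyp51, the lanosterol demethylase, fell from 322.5 ± 10.3 to 232.8 ± 4.94 CPM. In that list 2 members were lower when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.000343; adjusted p = 0.696 with an estimated correlation). In glycolysis and hypoxia, 21 of 23 were negative (median -0.23). In that list none changed by edgeR over all genes or when adjusted over the list alone, 1 was higher and 1 lower at an unadjusted p under 0.05, and DESeq2 called 0 (camera, Benjamini-Hochberg adjusted p = 0.00368; adjusted p = 0.818 with an estimated correlation). Slc2a1, a glucose transporter, measured 253.7 ± 30.2 and 194.4 ± 30.6 CPM, and Ero1l, an oxidase of the endoplasmic reticulum, 213.4 ± 10.02 and 246 ± 14.05 CPM in WT and Thbs2KO. Thbs2KO replicate 3 was the lowest library in the glycolysis and YAP lists, at -0.33 and -0.44. The glycolysis list did not pass the test without WT replicate 3 (camera, Benjamini-Hochberg adjusted p = 0.0974) or without Thbs2KO replicate 3 (adjusted p = 0.17). Without both WT replicate 1 and Thbs2KO replicate 3, an alternative added after the data were examined, the contractile and YAP lists were lower (camera, Benjamini-Hochberg adjusted p = 7.32e-14 and 0.00659), and the cholesterol and glycolysis lists did not pass the test (adjusted p = 0.068 and 0.199). Both calls were made at the preset correlation of 0.01. With all libraries the contractile and YAP lists had camera adjusted p = 0.696 and 0.27 with an estimated correlation. That estimate was 0.6 for the contractile list. For the YAP list it was 0.01, the same as the preset, so a higher correlation does not account for its lost call. Tested with fry, the contractile, YAP, cholesterol and glycolysis lists had unadjusted p of 0.0316, 0.00225, 0.0218 and 0.199. Collagen processing, not called by camera, had a fry p of 0.00695.

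In the collagen, glycoprotein, collagen processing and protease lists 1 gene changed, Mmp19, which rose. By edgeR 0 of 21 collagens changed, with 4 higher and 3 lower at an unadjusted p under 0.05 and 3 higher and 1 lower by DESeq2. Col15a1 measured 86.6 ± 51.7 CPM in WT and 759.9 ± 472 CPM in Thbs2KO, and Col6a2 539.1 ± 44.2 and 1105 ± 450 CPM (edgeR, Benjamini-Hochberg adjusted p = 0.1 and 0.155). Among 35 matrix glycoproteins and proteoglycans edgeR called 0, with 6 higher and 7 lower at an unadjusted p under 0.05 and 2 higher and 4 lower by DESeq2. Ogn and Fmod had log2 fold changes of 2.02 and -1.90. Thbs2KO replicate 3 stood highest in this list, at 0.61, and in the fibroblast markers, at 0.78. Of 20 collagen processing genes edgeR called 0 over all genes (2 higher and 6 lower at an unadjusted p under 0.05, 1 higher and 4 lower by DESeq2), and 1 was higher and 3 lower when adjusted over the list alone, among them Plod1 at 0.68 and Plod3 at -0.51. Among 24 proteases and inhibitors, Mmp19, a matrix metalloproteinase, rose from 120.6 ± 8.70 to 230.6 ± 23.3 CPM. Adjusted over the list alone, 1 was higher and 4 lower. In the TGF-beta list of 19 tested genes, Ccn2 and Ltbp2 fell and Ltbp1, which anchors latent TGF-beta in the matrix, rose from 105.6 ± 32.4 to 334.7 ± 58.0 CPM. In that list 4 were higher and 4 lower when adjusted over the list alone. In the angiogenic list of 16, Sema3c rose and Fgf2 fell, with 1 higher and 3 lower when adjusted over the list alone. Without WT replicate 2 that list was lower (camera, Benjamini-Hochberg adjusted p = 0.03), while with all libraries it had an adjusted p = 0.697 with an estimated correlation. In the thrombospondin family and receptor list of 16, edgeR called 0, with 2 higher and 2 lower at an unadjusted p under 0.05, 1 lower by DESeq2 and 1 lower when adjusted over the list alone. Comp and Stim1 had log2 fold changes of -2.63 and -0.33. Comp was near the floor, at 0.927 CPM in WT and 0.145 CPM in Thbs2KO (65 and 9 reads summed over each group). Of 22 niche, Wnt and BMP genes edgeR called 0, with 4 higher and 3 lower at an unadjusted p under 0.05 and 1 higher and 1 lower by DESeq2. Ereg and Dkk2 had log2 fold changes of -1.03 and 1.74. Dkk2 measured 289.8, 229.9 and 818.4 CPM in Thbs2KO replicates 1, 2 and 3. Its log2 fold change ran from 0.96 to 2.05 with 1 library left out. Camera did not separate any of these lists from the other genes, with Benjamini-Hochberg adjusted p of 0.927 for collagens, 0.914 for matrix glycoproteins, 0.126 for collagen processing, 0.975 for proteases, 0.914 for TGF-beta, 0.19 for angiogenic factors, 0.914 for thrombospondins and 0.506 for the niche list.

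In the immune lists 0 genes changed by edgeR. In the inflammatory list of 26 tested genes 1 was higher and 9 lower at an unadjusted p under 0.05, DESeq2 called 1 higher and 5 lower, and 3 were lower when adjusted over the list alone. C3 measured 15.3 ± 2.91 and 6.08 ± 1.51 CPM and Il11 4.85 ± 1.03 and 2.13 ± 0.254 CPM in WT and Thbs2KO. Of the chemokines that recruit T cells and dendritic cells 3 of 13 reached testable counts; Cx3cl1 and Cxcl10 had log2 fold changes of 0.36 and -0.19. Median log2 fold changes were -0.20 for 38 interferon response genes, 0.03 for 18 MHC class I genes (mean -0.03, camera downward), -0.57 for 4 tested MHC class II genes and -0.01 for 13 checkpoint and suppressive genes. In the chemokine, interferon and both MHC lists 0 genes had an unadjusted p under 0.05 and DESeq2 called 0. Of the checkpoint genes 1 was higher and 2 lower at an unadjusted p under 0.05, and 1 was lower by DESeq2 and when adjusted over the list alone. Pvr, a ligand of the lymphocyte receptor TIGIT, measured 156.5 ± 47.8 CPM in WT and 68.6 ± 12.6 CPM in Thbs2KO. Examples of the other lists were Gbp2 and Ifi47 (-0.60 and -0.61), H2-M3 and Nlrc5 (-0.39 and 0.36), Slpi and H2-Ab1 (-1.37 and -0.82) and Cd276 (-0.37). By edgeR and by DESeq2, 0 of 30 cell cycle genes and 0 of 22 ATF4 or unfolded protein response genes changed, with 0 and 2 at an unadjusted p under 0.05. Tyms, Cenpe, Ddit4 and Chac1 had log2 fold changes of 0.37, -0.32, -0.29 and -0.49. Camera gave Benjamini-Hochberg adjusted p of 0.126 for the inflammatory list, 0.927 for chemokines, 0.997 for interferon and for MHC class I, 0.1 for MHC class II, 0.776 for checkpoint genes, 0.927 for cell cycle and 0.506 for ATF4. Interferon genes stood at 1.66 in WT replicate 1 and 1.36 in Thbs2KO replicate 3, against -0.67 to -0.88 in the other 4 libraries (mean log2 CPM relative to the 6), and MHC class I genes at 0.54 and 0.37 against -0.06 to -0.35. Camera called the interferon list higher in Thbs2KO without WT replicate 1 and lower without Thbs2KO replicate 3 (Benjamini-Hochberg adjusted p = 0.00258 and 0.021). Those calls rest on the preset correlation of 0.01, against 0.96 estimated for that list with all libraries (adjusted p = 0.999 with an estimated correlation). Camera called the inflammatory and MHC class II lists lower without WT replicate 2 (Benjamini-Hochberg adjusted p = 0.00521 for each) and the cell cycle list higher without Thbs2KO replicate 3 (adjusted p = 0.000419), whose own level was -0.51. With all libraries these 3 lists had adjusted p of 0.698, 0.697 and 0.999 with an estimated correlation, which for cell cycle was 0.95.

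**Figure D3:**
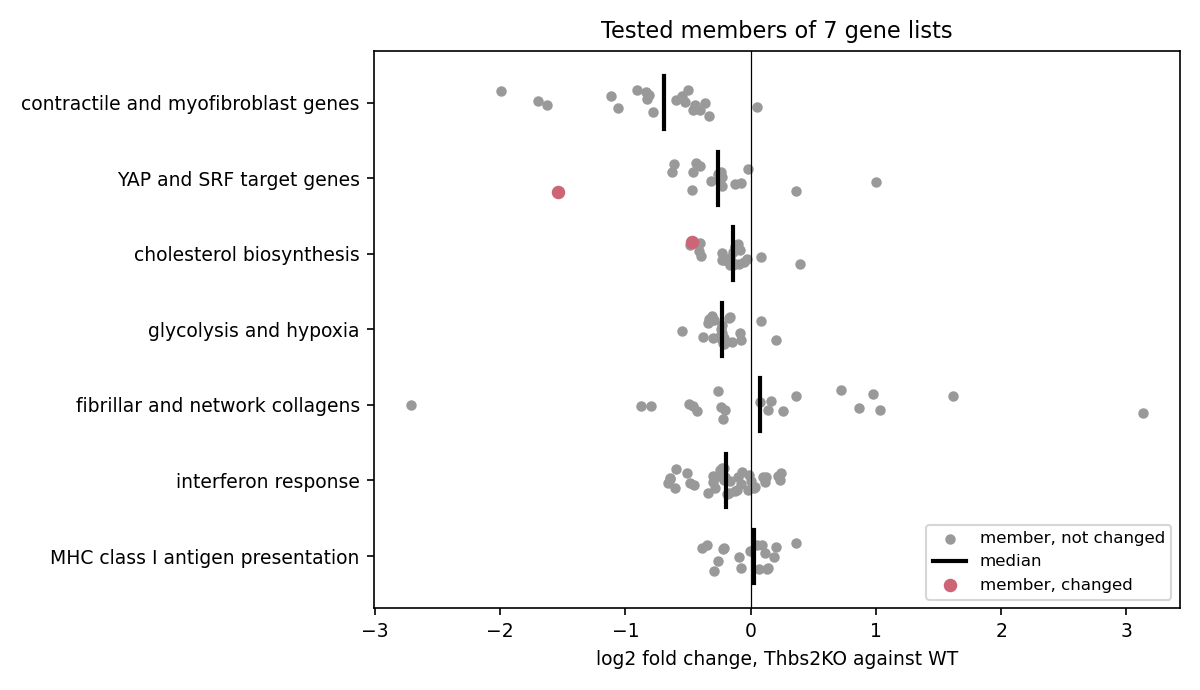
Log2 fold change of Thbs2KO against WT (horizontal axis) of each tested member of 7 gene lists; grey points did not change, red points changed, and black bars are medians. The contractile list has its median at -0.69 and the interferon list at -0.20; vertical scatter within a list has no meaning.

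The epithelial and tumour organoid list was lower in Thbs2KO (camera, Benjamini-Hochberg adjusted p = 0.000871; adjusted p = 0.139 with an estimated correlation; unadjusted fry p = 0.00455), with 9 of 20 markers tested. By edgeR 0 of them changed over all genes, 3 were lower at an unadjusted p under 0.05 and 2 when adjusted over the list alone or by DESeq2. Krt19, its most abundant member and chosen after its values were seen, measured 12.8 ± 2.53 CPM in WT and 5.18 ± 1.42 CPM in Thbs2KO. As mean log2 CPM relative to the 6 libraries, the epithelial list stood at 0.23, 0.75 and 0.93 in WT and -1, -0.81 and -0.1 in Thbs2KO. Thbs2KO replicate 3 thus lay nearest to WT replicate 1. Of 14 fibroblast markers edgeR called 0, with 1 higher at an unadjusted p under 0.05 and by DESeq2 (median 0.33, camera, Benjamini-Hochberg adjusted p = 0.342). For leukocytes 4 of 20 and for endothelium 6 of 16 markers reached testable counts, with 0 changed by edgeR and 1 endothelial marker lower at an unadjusted p under 0.05, when adjusted over the list alone and by DESeq2 (camera, Benjamini-Hochberg adjusted p = 0.746 and 0.952). Of the mesothelial, glial and neuronal, skeletal muscle and adipocyte markers, 3 each were tested and edgeR called 0 over all genes (camera, Benjamini-Hochberg adjusted p = 0.952, 0.952, 0.746 and 0.891). Adjusted over the list alone and by DESeq2, 1 mesothelial and 1 skeletal muscle marker were lower and 1 glial or neuronal marker was higher and 1 lower. The mesothelial one was Krt19, also a member of the epithelial list, so it is not separate evidence. The other 2 tested mesothelial markers had positive log2 fold changes, 1 of them at an unadjusted p under 0.05 by edgeR. Median and mean differed in sign for the glial and neuronal list (-0.22 and 0.45, camera upward) and for the adipocyte list (0.31 and -0.05, camera upward). Among quality lists, 0 of 13 mitochondrially encoded and 0 of 4 sex-linked genes changed by edgeR, with 3 and 0 at an unadjusted p under 0.05 and 1 and 0 by DESeq2 (camera, Benjamini-Hochberg adjusted p = 0.0666 and 0.336).

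Changed genes were denser on chromosome 17, which carries Thbs2, than elsewhere: 20 of 672 tested genes (2.98%), 16 of them lower. Chromosome 3 had 19 of 679 (2.80%) and chromosome 14 had 11 of 461 (2.39%), while chromosome 11 had 2 of 1074 (0.186%). Leaving out Thbs2 and pseudogenes, 14 of 330 tested genes within 20 Mb of Thbs2 changed (4.24%), against 0.865% elsewhere, and 13 of the 14 were lower. Among them were Rnaset2b, Zdhhc14, Rsph3a, Atp6v0c and Sik1, with log2 fold changes of -1.66, -2.15, -1.13, -0.71 and -1.99, named after their values were seen except for Rnaset2b and Sik1. Off chromosome 17, named genes with a changed neighbour within 1 Mb included Apoe, Fgf2, Fgf2os, Ntn4, AI506816, Unc5c, Rtl3, Srp54b, Uggt2, Dixdc1 and Fhdc1. For these genes an effect of Thbs2 loss was not separated from one of position.

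**Figure D4:**
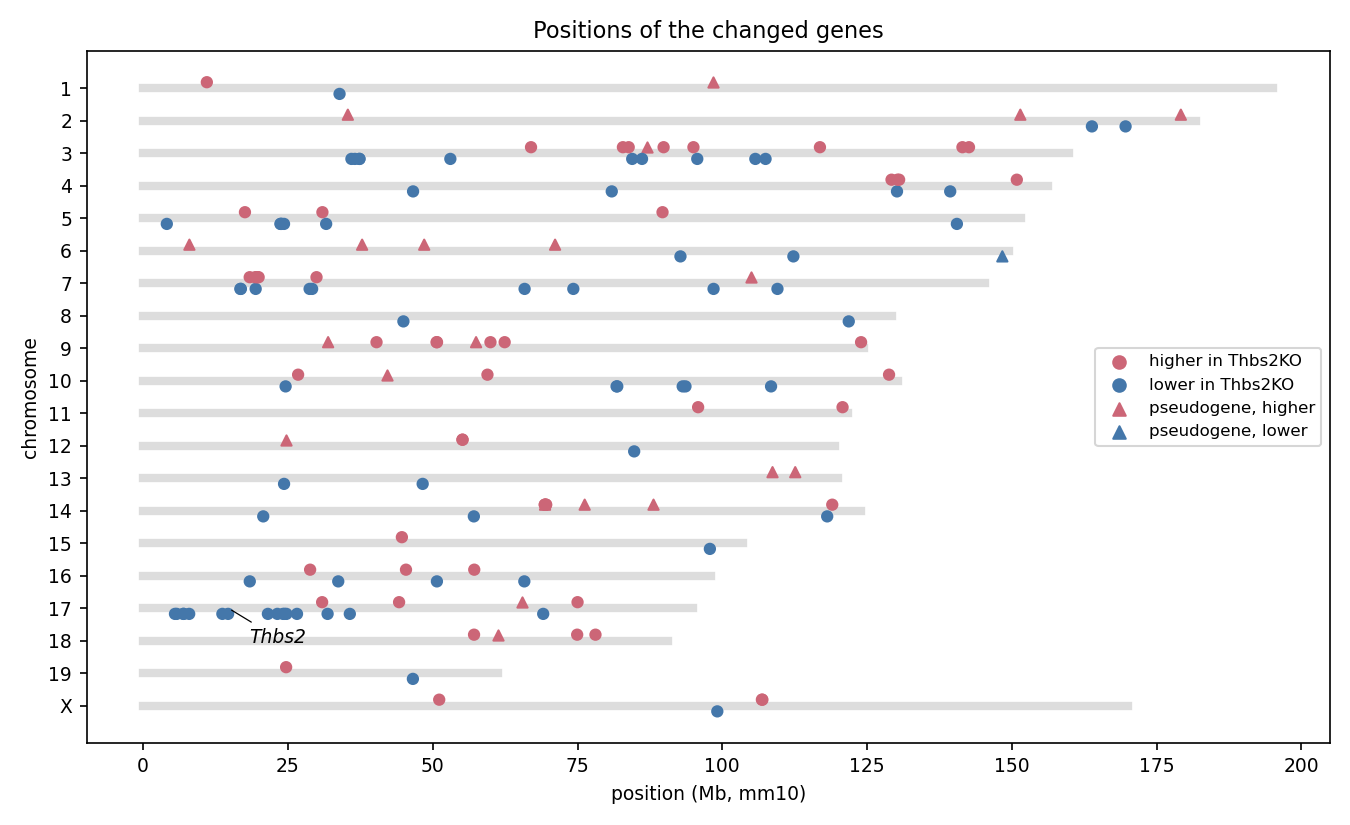
Position in Mb (mm10, horizontal axis) of the 148 changed genes on each chromosome (vertical axis), red where higher and blue where lower in Thbs2KO, triangles for pseudogenes. Grey bars run to the last tested gene; chromosome 17 has 20 changed genes, 16 of them lower.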

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

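The alternatives that drop both WT replicate 1 and Thbs2KO replicate 3, sum Thbs2KO replicates 1 and 2, keep protein-coding genes only or leave out chromosome 17 were chosen after the data were examined. The 148 changed genes became 699 with DESeq2, 245 with no filter on low counts and 49 with a tested minimum of 1.5-fold. They became 1519 without both WT replicate 1 and Thbs2KO replicate 3, 40 with Thbs2KO replicates 1 and 2 summed and 86 among protein-coding genes only, where fewer genes were tested. With 1 library left out the count ran from 38 to 397. The replicate numbers gave no clear sign of pairing the samples: deviations of same-numbered libraries correlated at -0.29, 0.17 and -0.33, against -0.3 to 0.4 for different numbers. With 3 libraries per group this cannot exclude pairing. With the replicate block 30 genes changed, 28 of them among the 148. Without chromosome 17 Thbs2 itself is left out and has no value. Single genes were not evaluated with the tested minimum of 1.5-fold. Thbs2 was lower in each of the 17 alternatives that gave it a value, with a log2 fold change of -2.86 and an edgeR Benjamini-Hochberg adjusted p of 0.0784 in the replicate block, and from -3.10 to -2.71 with 1 library left out, where the adjusted p ran from 0.00116 to 0.0477. The 4 process lists became 0 with the correlation estimated, 2 without both libraries and 3 to 7 with 1 library left out; the 1 cell type list became 0 with the correlation estimated and 2 with the stricter filter, without both libraries, among protein-coding genes or without chromosome 17, and 1 to 2 with 1 library left out. Reversed against the original direction, the interferon list was higher without WT replicate 1 and the cell cycle list without Thbs2KO replicate 3: with 1 library left out, camera Benjamini-Hochberg adjusted p ran from 0.00258 to 0.348 for interferon and from 0.000419 to 0.978 for cell cycle. Both rest on the preset correlation: with all libraries the estimates were 0.96 for interferon and 0.95 for cell cycle, each with a camera Benjamini-Hochberg adjusted p = 0.999 with an estimated correlation. A further 48 list values and 13 gene values changed sign where neither value passed the threshold. RLE and upper-quartile scaling shifted the median log2 fold change by 0.005. Except where stated, the cause was not tested. The simulation, which drew genes independently, called 13 of 50 genes changed 1.5-fold, so smaller changes were mostly not detectable. Its rates may not hold for these libraries, where genes vary together.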

Other observations

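Except for the splits of the samples, the tests of explanations reported here were chosen after the results they bear on were seen. Each of 3 tests replaced an earlier version after its value was seen: independent transcription was first judged by the lower end of the ratio of parent loss to copy gain in 4 parents, 0.79, reads shared with a parent by the median ratio in these 4, 1.39, and RNA like that of the WT libraries by a search for at least 3 transcripts kept under 6.06%, which found 2 and left it open.

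Interferon-stimulated genes differed between libraries of the same genotype. Isg15, an antiviral ubiquitin-like protein, measured 75.2, 4.16 and 3.31 CPM in the WT libraries and 3.92, 5.33 and 56.1 CPM in the Thbs2KO libraries. Ifit3 measured 57.2, 5.43 and 3.14 CPM in WT and 6.57, 5.24 and 65.6 CPM in Thbs2KO, and the MHC class I light chain B2m 368.8, 203.4 and 219.9 CPM and 218.1, 240.3 and 440.6 CPM. WT replicate 1 and Thbs2KO replicate 3 were thus high in both gene groups. Thbs2KO replicate 3 was also the highest in Ogn, 770.6 CPM against 368.5 and 267.7 CPM in the other Thbs2KO libraries, and in Mgp, a matrix calcification inhibitor, 490.2 CPM against 82.5 and 88.7 CPM.

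The edgeR test called 148 genes for the real grouping and at most 0 for the other splits of the 6 libraries into 3 and 3; 1 of the 10 splits, the real grouping itself, called as many, and 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05, the real grouping had 1806 genes and the highest of the others 1728.

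Pseudogene copies rose while changed genes lay close together on chromosomes. Independent transcription of the copies would leave their parents spread like those of other pseudogenes, but 7 of 17 parents (41.2%) lie on chromosome 17, against 18 of 295 (6.10%), a Fisher odds ratio of 10.59 (95% interval 3.05 to 35.36). Reads of a parent counted on its copy cannot be told apart: over all 17 parents, the parent's loss divided by the copies' gain had a median of 2 (95% bootstrap interval 0.79 to 3.78) and ran from -6.6 for Cd1d1 to 242.64 for Loxl2, with 3 parents higher in Thbs2KO, and in the 4 parents whose copies gained at least 20% of the parent's WT level it had a median of 1.39 (range 0.79 to 2.07). Where the gain is small the ratio cannot test this, as for Loxl2, whose copy gained 0.141% of the parent's WT level. Summed with its copies, Rps3a1 measured 855.7 CPM in WT and 954.3 CPM in Thbs2KO, and Rpl34 282.8 and 290.5 CPM. Summed in the same way, Atp6v0c fell from 281.6 to 201.7 CPM and Rnps1 from 103.7 to 84.01 CPM. A candidate source is chromosome segments that differ in sequence between the WT and Thbs2KO mice, since, leaving out Thbs2 and pseudogenes, the odds of change within 20 Mb of Thbs2 were 5.08 times those elsewhere (95% interval 2.66 to 9), and off chromosome 17, 48 of the 107 changed genes that are not pseudogenes had a changed neighbour within 1 Mb against a median of 17 in random draws (permutation p = 1e-04, the smallest that 10000 draws can give). The random draws treat genes as independent. Some of the 48 overlap, as Fgf2 and Fgf2os do, and can share reads, which may inflate that count. Shared regulation of neighbours and an effect of Thbs2 loss itself were not tested, the breeding of the mice is not given in the sources used here, and sequence variants cannot be read from counts.

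Thbs2 kept 13.5% ± 2.04 (SD, n = 3) of its WT level in Thbs2KO. RNA like that of the WT libraries in the Thbs2KO libraries would bring every abundant WT transcript at the share of Thbs2, which ran from 9.89% to 23.1% over the 9 pairings of a Thbs2KO with a WT library. The tables argue against it as the whole source: AI506816 kept 1.19% of its WT mean of 393.7 CPM, and its upper counting bound, adjusted for the 9073 transcripts searched, allows at most 2.7%. Ntn4, which kept 5.22%, also had its bound below the share of Thbs2 within each pairing, but at 16.3% of the lowest WT library that bound exceeds 9.89%, so by the lowest share the argument rests on AI506816 alone. Cells with an intact Thbs2 that lack these 2 transcripts and transcription from the targeted allele remain open and were not tested.

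Contractile genes were lower in Thbs2KO by camera at the preset correlation only (adjusted p = 0.696 with an estimated correlation), and WT replicate 1 stands near the Thbs2KO libraries. Members on chromosome 17 or within 1 Mb of a changed gene do not alone account for it. At the preset correlation the list was also lower without them (camera, Benjamini-Hochberg adjusted p = 1.35e-09, 18 of 20 members left). Few members were thus dropped, and wider segments were not tested. A smaller share of smooth muscle cells and pericytes would lower their other markers too, and it cannot be told apart: the 7 tested markers outside the contractile list had a median log2 fold change of -0.18 ± 0.50 (SD over markers), higher than that of the list by 0.51 (95% bootstrap interval 0.11 to 0.89, which measures spread over genes, not over libraries). Of these markers 2 were lower when adjusted over the list alone, Mcam (log2 fold change -1.21) and Smtn (-0.41), both with an edgeR Benjamini-Hochberg adjusted p of 0.00805 over that list. An effect of Thbs2 loss on contractile genes remains an untested hypothesis, which these libraries cannot separate from other differences between the groups.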
